A study of Mus musculus with 16 samples.

How the data were processed

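H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse small-intestinal epithelium. There were 4 groups with 2 libraries each: epithelium of embryonic day 12.5 (E12.5), epithelium of embryonic day 14.5 (E14.5), Lgr5-positive intestinal stem cells (ISC) and enterocytes, the absorptive cells of the villus. The adult cells came from postnatal day 60. Per the labels' protocols, embryonic cells and enterocytes were sorted as positive for EpCAM, an epithelial surface protein, and negative for the endothelial marker CD31 and the leukocyte marker CD45. ISC were sorted from crypts for high GFP from the Lgr5 locus. The adult mice were males, and the sex of the embryos is not given in the sources used here. The series describes each pair of libraries as biological duplicates. Each ChIP library has its own input library, and the 8 input libraries enter here only through the peak calls.

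Per the submitters' processing notes, bcl2fastq 1.8.4, Bowtie 1.1.2, SAMtools 1.2 and MACS2 were used and the genome build was mm9. Per the file headers, peaks were called for each library separately against its input with MACS 2.1.0.20140616, in the narrow mode, at a q-value threshold of 0.05. Per the file headers, the tags were 51 bp long, 1 tag was kept per position and the larger of ChIP and input was scaled to the smaller. Each deposited list gives the start, end and length of a peak, the pileup at its summit (a coverage signal), −log10 p and −log10 q, and a fold enrichment over the local background. Per the file headers, the pileup signal, the −log10 values and the fold enrichment ratio are the output of MACS. These scores are the authors' and belong to each list, so they served only to rank or filter peaks within a list. The ChIP libraries held 34.6 to 54.6 M tags and the inputs 35.0 to 38.8 M. Counts per region were not used here, so no interval from counting error is given and the precision rests on the 2 libraries per group.

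From the lists, the peaks of the libraries compared were merged where they overlapped or touched, and a library had a region when it had at least 1 bp of peak in it. A region was called gained when every library of the later group and no library of the earlier group had it, and lost in the reverse case. A permutation test of a single region with 2 libraries a group cannot give p under 0.05, so presence in all against none was the rule. The counts were therefore set beside those from every other split of the same libraries into groups of the same sizes. For 2 against 2 libraries there are 3 splits, and for 4 against 4 there are 35. Libraries of a group resemble each other, so splits that part replicates give few regions, and only 3 of the 35 keep replicates together. Exact tests of 4 adult against 4 embryonic libraries likewise shuffle all 8 libraries freely, as if replicates were no more alike than other libraries. Similarity of peak sets was measured by the Jaccard index, the shared length over the length in either set. An exact permutation test compared its mean over the replicate pairs with that of all 105 ways to pair the 8 libraries. Other p-values for values per library come from exact two-sided permutation tests. All p-values measure the spread between these libraries, except those for the nearness of changed regions. The latter come from random draws of regions and hold no spread between libraries.

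The gene table supplied is on the assembly GRCm38.p6 and not on mm9, and coordinates were not converted. For that reason the regions are given by position on mm9 without gene names, and the share of peaks at promoters and the tests on genes and on gene lists that had been planned are not reported here. The rule for named regions was fixed before the data were examined: for each comparison the 2 gained and the 2 lost regions with the greatest length, taken as the smaller of the libraries' covered lengths. The parts of that rule that concern genes could not be applied. In place of the planned gene windows, fixed windows of 20 kb were analysed, a choice made after seeing the data. The length covered by peaks in each window was scaled by the library's total covered length to the mean of the 8 libraries. Windows with a peak in at least 2 libraries were kept, and log2(covered bp + 500) was fitted with limma (lmFit, then eBayes with trend and robust). The model had 4 group means with 4 residual degrees of freedom, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Changes on this scale depend on the added 500 bp, so covered lengths as deposited are printed for windows and no fold is given against groups without peaks. The windows named are the 2 with the largest change in each direction whose groups of libraries did not overlap, at least 40 kb apart, also chosen after seeing the data.

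The scripts were tested on simulated data. For the regions, artificial peak lists were made for 2 groups of 2 libraries, without use of the E12.5 or E14.5 lists. The artificial peaks were short and too far apart to merge with neighbours, so the rates below need not hold for real lists. All 200 planted gained and 100 planted lost regions were found among 5000 unchanged ones. When 10% of peaks were dropped at random from each library, 85.5% of the gained and 76.0% of the lost regions were found. Of the 212 gained and 119 lost calls made, 84 were wrong. Real replicates overlapped in 82.1% of peaks on average, so this drop may be milder than in the data. For the windows, 30733 windows with the spread of the real libraries were simulated for E14.5 against E12.5, 200 of them changed. Of those changed 2-fold, 9% were called, and of those changed 4-fold, 41% were called, with 1 false call among 51. Without any planted change 0 windows were called. All groups shared 1 mean in each unchanged window of this simulation. Groups without peaks beside groups with several kb, as in many of the windows named below, were not simulated. The counts of false calls therefore do not carry over to such windows.

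Alternatives fixed before the data were examined were a stricter peak threshold (−log10 q of at least 10), the 35614 highest-ranked peaks of each library, a cover of at least 50% of a region, merging of peaks within 1 kb, and leaving out each library in turn. For the windows they were added after seeing the data and comprised pseudocounts of 100 and 2000 bp, no scaling, quantile normalization, windows of 10 and 50 kb, both peak filters, no filter on libraries, the fit without trend and robust, the replicate number as a block, a fit with 2 groups for adult against embryo, and each library left out. The analysis used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.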

Results

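Active chromatin was followed through intestinal development by profiling H3K27ac in sorted epithelial cells at 4 points: the gut epithelium of E12.5 and E14.5 embryos, the adult Lgr5-positive stem cells of the crypts (ISC), and the adult enterocytes. Each group had 2 libraries. The libraries held 37.9 and 40.4 M ChIP tags at E12.5, 38.6 and 54.6 M at E14.5, 40.4 and 42.1 M in ISC, and 42.2 and 34.6 M in enterocytes.

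Enterocytes had the fewest called peaks of the 4 groups. Their libraries held 36027 ± 583 peaks (mean ± SD, n = 2), against 48209 ± 5112 in ISC, 50726 ± 2316 at E14.5 and 49610 ± 4101 at E12.5. Peaks covered 38.8 ± 0.0198 Mb in enterocytes and 63.7 ± 17.6 Mb in ISC, where the replicates differed most, with 51.2 and 76.1 Mb. E14.5 libraries covered 61.0 ± 5.77 Mb and E12.5 libraries 51.8 ± 11.6 Mb. ISC replicate 2 also had the most peaks of at least 10 kb, 342 against 85 in ISC replicate 1 and 20 to 116 in the other 6 libraries. The 4 adult libraries averaged 42118 ± 7635 peaks and the 4 embryonic ones 50168 ± 2794, a difference that an exact permutation test did not separate (p = 0.114, two-sided). Across the 8 libraries the number of peaks did not follow the ChIP tags (Pearson r = 0.29, exact permutation p = 0.495; Spearman rho = 0.24, exact permutation p = 0.582; adjusted p = 0.892 and 0.793 over 4 relations). Without the 2 libraries farthest from the median depth, r was −0.35.

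**Figure D1:**
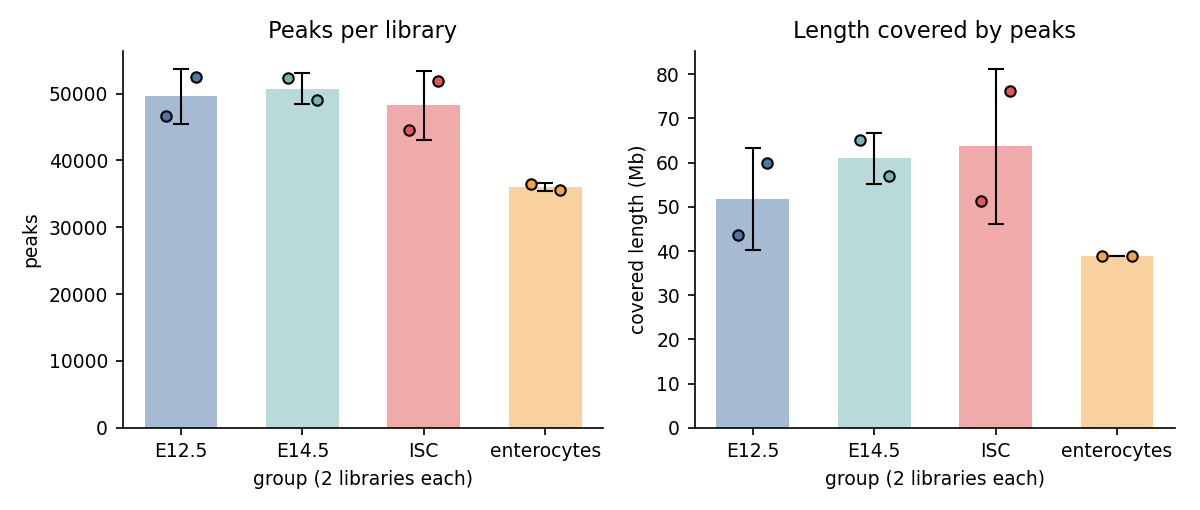
Number of peaks (left) and length of the genome covered by peaks in Mb (right) in each group. Bars are means of 2 libraries, error bars 1 SD and points the libraries; enterocytes lie lowest in both panels, at 36027 peaks and 38.8 Mb on average.

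The longest peak lay at the same locus in all 4 embryonic libraries, on chromosome 14 between 63845742 and 63878062, where it was 27982 to 32227 bp long. In both ISC libraries the longest peak lay on chromosome 6, from 94613674 to 94650220 in replicate 1 and from 94613096 to 94653292 in replicate 2. The longest enterocyte peaks were on chromosome 11 (97659970 to 97683641) in replicate 1 and on chromosome 9 (46035330 to 46052606) in replicate 2. All positions are on mm9.

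By the Jaccard index, replicates resembled each other more than libraries of different groups did. The share of overlapped peaks separated them only on average. A mean of 82.1% of the peaks of a library overlapped a peak of its replicate (SD 13.4, 8 values, 61.0 to 98.7%). For libraries of different groups the mean was 59.0% (35.6 to 84.5%). Of the peaks of E12.5 replicate 2, 66.4% overlapped its replicate and 75.2% overlapped E14.5 replicate 1. The Jaccard index of replicate pairs averaged 0.702 (0.659 to 0.771) and that of other pairs 0.414 (0.258 to 0.605). Of the 105 ways to pair the 8 libraries, the real one gave the highest mean (exact permutation p = 0.00952, the smallest possible). Between groups, the similarity was highest for E12.5 and E14.5 (Jaccard index 0.571 ± 0.0322, SD over 4 pairs of libraries), followed by E14.5 and ISC (0.496 ± 0.00889) and by ISC and enterocytes (0.420 ± 0.0398). It was lowest for E12.5 and enterocytes, at 0.276 ± 0.0162.

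**Figure D2:**
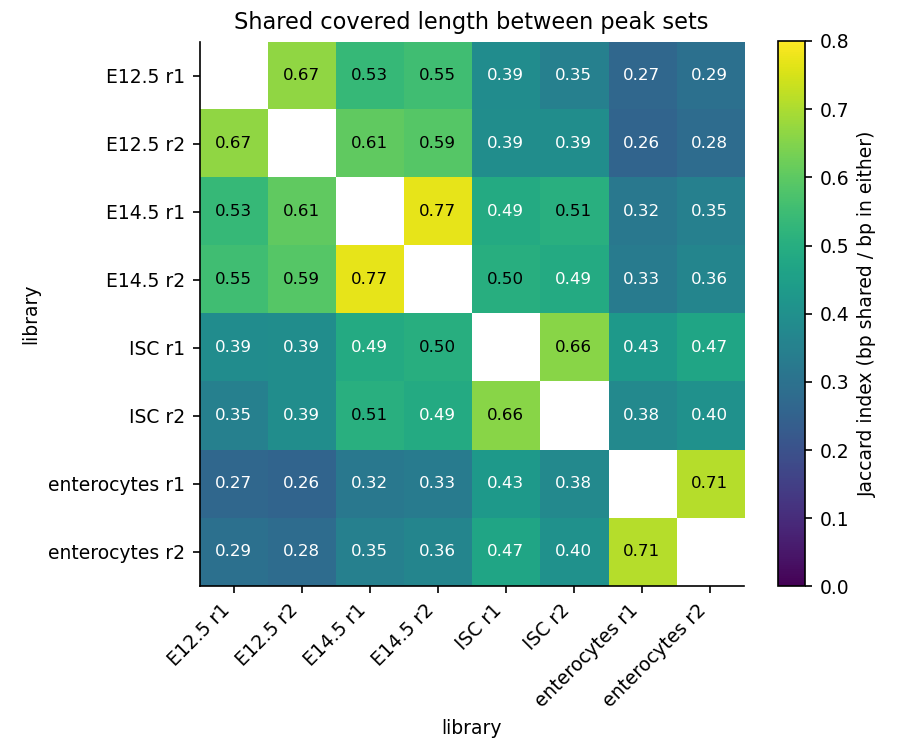
Jaccard index of the peak sets of each pair of the 8 libraries (r1 and r2 are replicates 1 and 2). Replicate pairs lie between 0.66 and 0.77, above the highest pair from different groups at 0.61.

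The comparison of E14.5 with E12.5 asks how active chromatin changed over this interval in the embryonic gut epithelium. More regions were gained than lost: 7726 regions were present in both E14.5 libraries and in neither E12.5 library, and 3622 showed the reverse, out of 62048 merged regions. A further 24271 regions were present in all 4 libraries, and 26429 were neither gained, lost nor in all libraries. The balance turned without E12.5 replicate 1 (8080 gained, 12174 lost) but held without E12.5 replicate 2 (11782 gained, 6657 lost). A group left with 1 library meets its criterion more easily, which by itself moves these counts. The longest gained region lay on chromosome 6 from 86720852 to 86727475, where peaks covered 6.33 ± 0.116 kb at E14.5 and none at E12.5, 6.62 ± 0 kb in ISC and 5.58 ± 0.241 kb in enterocytes (mean ± SD, n = 2). The next, on chromosome 1 from 67157287 to 67163696, had 6.08 ± 0.170 kb at E14.5 and 6.11 ± 0.199 kb in ISC. The longest lost regions were on chromosome 5 from 117116821 to 117125525, with 8.31 ± 0.396 kb at E12.5, and on chromosome 4 from 40254519 to 40261265, with 6.25 ± 0.301 kb. The first of these had no peak in any of the other 6 libraries, and the second had 0.663 kb in ISC replicate 2 only.

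Gained and lost regions together numbered 11348 for the study groups and at most 1593 for the other 2 splits of the 4 libraries. Both other splits part replicates, so this gap restates the likeness of replicates. The gained and lost regions were mostly weak within their own lists. By −log10 q, the median gained region stood at the 26th percentile of the E14.5 lists, and regions in all libraries at the 64th. In 20 kb windows, limma called 4398 windows with more and 3588 with less covered length at E14.5, of 30733 tested. The largest changes were a window on chromosome 6 (86720001 to 86740000), from 0 to 8.31 ± 0.759 kb (adjusted p = 0.000251), and a window on chromosome 7 (6800001 to 6820000), from 14.3 and 14.7 kb in the E12.5 libraries to 0.536 ± 0.0672 kb at E14.5 (adjusted p = 0.000264). A window on chromosome 11 (117200001 to 117220000) rose from 0.132 ± 0.187 to 9.74 ± 1.67 kb and was back at 0 in enterocytes. One on chromosome 12 (106140001 to 106160000) fell from 8.23 ± 0.593 to 0.148 ± 0.209 kb. The balance of windows was not stable: more fell than rose without E14.5 replicate 1 (2038 up, 2714 down) or replicate 2 (1916 up, 2183 down). Without scaling, limma called 3546 windows with more and 2094 with less covered length.

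**Figure D3:**
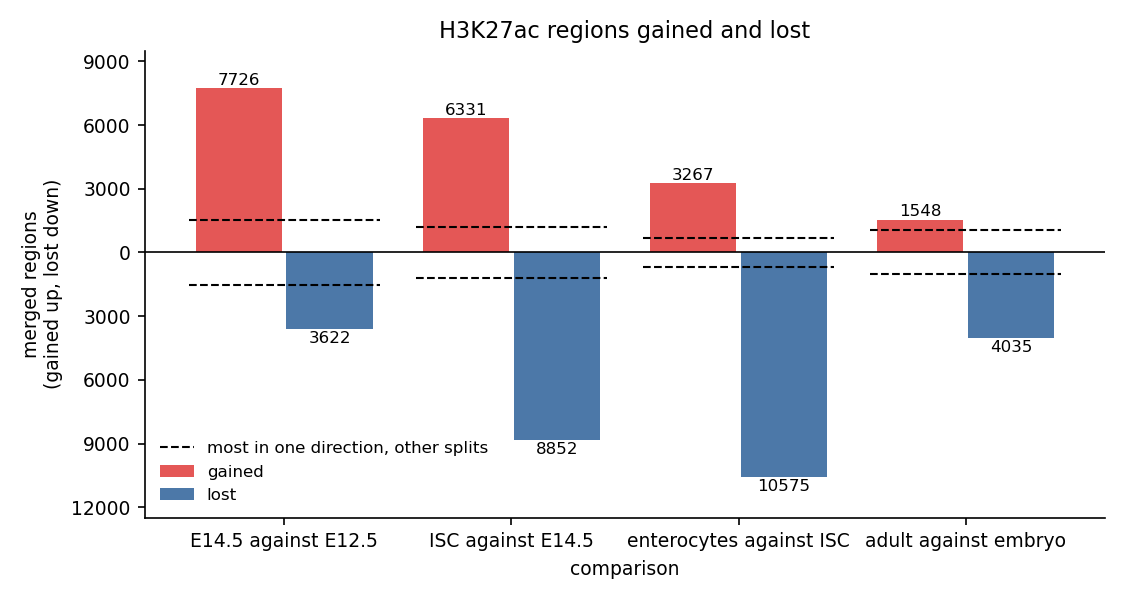
Merged regions gained (up) and lost (down) in the 4 comparisons. Dashed lines mark the most regions in a single direction from any other split of the same libraries (1540, 1205, 669 and 1036 from left to right); every bar exceeds its line.

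The step from E14.5 epithelium to adult ISC joins the embryonic tissue to the adult stem cells. Here 8852 regions were lost and 6331 gained, of 65741 merged regions, and 21876 were present in all 4 libraries. A further 28682 were neither gained, lost nor in all libraries. The balance turned without ISC replicate 1 (19372 gained, 8905 lost) but held without ISC replicate 2 (11499 gained, 12891 lost). Here too a group left with 1 library meets its criterion more easily. The longest lost region, on chromosome 7 from 149737507 to 149765255, was covered by peaks over 27.3 ± 0.300 kb at E14.5 and 27.2 ± 0.707 kb at E12.5, and had no peak in any adult library. The next, on chromosome 10 from 44200092 to 44210783, had 10.6 ± 0.0728 kb at E14.5, 9.38 ± 1.69 kb at E12.5 and none in the adult libraries. The longest gained regions were on chromosome 12 from 78292926 to 78301524, with 8.45 ± 0.218 kb in ISC and 5.53 ± 1.52 kb in enterocytes, and on chromosome 17 from 16136314 to 16145204, with 8.39 ± 0.704 kb in ISC alone.

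Gained and lost regions together numbered 15183, against at most 1215 for the other 2 splits, which both part replicates. In the windows, limma called 5107 with more and 6658 with less covered length in ISC. On chromosome 17 (15940001 to 15960000) peaks covered 0 kb at E14.5, 15.5 ± 1.38 kb in ISC (adjusted p = 8.29e-05) and 1.13 ± 0.399 kb in enterocytes. On chromosome 15 (85500001 to 85520000) they covered 0.113 ± 0.160 kb at E14.5, 18.1 ± 1.25 kb in ISC (adjusted p = 0.000126) and 13.1 ± 0.342 kb in enterocytes. The windows with the largest losses lay on chromosome 7, from 149740001 to 149760000 (20.0 ± 0.0431 kb to 0, adjusted p = 5.5e-05) and from 149840001 to 149860000 (13.8 ± 0.149 kb to 0, adjusted p = 5.6e-05). The excess of losses nearly closed among peaks with −log10 q of at least 10, with 3602 regions gained and 3840 lost and 3163 windows up and 3560 down. With a library left out, falling windows always outnumbered rising ones, but the calls went down to 3086 rises without ISC replicate 2 and 4063 falls without E14.5 replicate 1.

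Enterocytes descend from ISC, and their comparison asks how active chromatin changed on differentiation. Losses outnumbered gains by 3.24 to 1, among 57825 merged regions. Of these, 10575 regions of ISC were absent from both enterocyte libraries, and 3267 regions of enterocytes were absent from both ISC libraries. A further 26988 were neither gained, lost nor in all libraries. The longest lost region, on chromosome 14 from 80398690 to 80416407, had 16.7 ± 1.43 kb in ISC, none in enterocytes or at E12.5, and 0.245 kb in 1 E14.5 library. The next, on chromosome 11 from 108957857 to 108970401, grew from 2.62 ± 0.873 kb at E12.5 and 4.87 ± 0.252 kb at E14.5 to 12.1 ± 0.677 kb in ISC, and had no peak in enterocytes. The longest gained regions were on chromosome 7 from 88256867 to 88263730, with 6.75 ± 0.111 kb in enterocytes, and on chromosome 19 from 34590149 to 34596141, with 5.84 ± 0.0530 kb; at E14.5 the first had 0.760 ± 0.298 kb.

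Gained and lost regions together numbered 13842, against at most 682 for the other 2 splits, which both part replicates. The lost regions included 189 of the 10087 regions at or above the 75th percentile of both ISC lists. In the windows, limma called 4153 with more and 7571 with less covered length in enterocytes, so that 35.4% of calls were higher. Without scaling for the total covered length, 1552 windows were higher and 10094 lower (13.3% higher), and the median change over all windows moved from 0 to −0.41 on the log2 scale. A window on chromosome 2 (13400001 to 13420000) had 6.36 ± 1.33 kb at E12.5 and 6.83 ± 0.745 kb at E14.5, no peak in ISC, and 14.7 ± 1.15 kb in enterocytes (adjusted p = 4.93e-05). One on chromosome 11 (118840001 to 118860000) likewise went from 5.85 ± 0.783 kb at E14.5 to 0.616 ± 0.870 kb in ISC and 14.6 ± 4.54 kb in enterocytes (adjusted p = 0.000895 against ISC). The largest losses from ISC were on chromosome 14, from 75300001 to 75320000 (16.1 ± 3.14 kb to 0) and from 80400001 to 80420000 (15.6 ± 1.48 kb to 0), with adjusted p-values of 4.93e-05 and 6.91e-05. The ratio fell to 1.70 (7317 lost, 4299 gained) with equal numbers of peaks per library. With a library left out it ranged from 1.69 without enterocytes replicate 2 to 8.16 without ISC replicate 1. With a library left out, falling windows always outnumbered rising ones, but the calls went down to 2571 rises without enterocytes replicate 1 and 4862 falls without ISC replicate 2.

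Adult and embryonic epithelium were compared over all 8 libraries. Of 79482 merged regions, only 1548 were present in all 4 adult and no embryonic library, and 4035 in all 4 embryonic and no adult library. A further 12282 were present in all 8, and 61617 were in none of these classes. The longest adult regions were on chromosome 15 from 85528300 to 85539870, with 9.91 ± 1.17 kb (n = 4), and on chromosome 4 from 148157341 to 148166165, with 8.26 ± 0.642 kb. The longest embryonic regions were the one on chromosome 7, here from 149737366 to 149765568, with 27.5 ± 0.540 kb, and one on chromosome 6 from 49168141 to 49179161, with 10.6 ± 0.365 kb. Gained and lost regions together numbered 5583. Of the other 2 splits that keep replicates together, that of E12.5 and enterocytes from E14.5 and ISC gave 1061 and that of E12.5 and ISC from E14.5 and enterocytes gave 203. With equal numbers of peaks per library, 1714 regions were gained and 2926 lost.

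In the windows, limma called 8125 with more and 12447 with less covered length in the adult. These calls rest on the spread between replicates; a fit with 2 groups, which also counts the differences among the groups of each age, called 3039 windows up and 5467 down. On chromosome 4 (137900001 to 137920000) peaks covered 0 kb in the embryo and 11.1 ± 4.74 kb in the adult (n = 4, adjusted p = 5.32e-06), with 7.25 ± 2.29 kb in ISC and 15.0 ± 1.45 kb in enterocytes. The window on chromosome 15 from 85500001 to 85520000 rose from 0.110 ± 0.127 to 15.6 ± 3.00 kb (adjusted p = 1.48e-05). On chromosome 8 (35000001 to 35020000) peaks covered 13.7 ± 1.05 kb in the embryo and 0 in the adult (adjusted p = 5.32e-06), and on chromosome 7 (149740001 to 149760000) 20.0 ± 0.0588 kb and 0 (adjusted p = 5.57e-06).

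**Figure D4:**
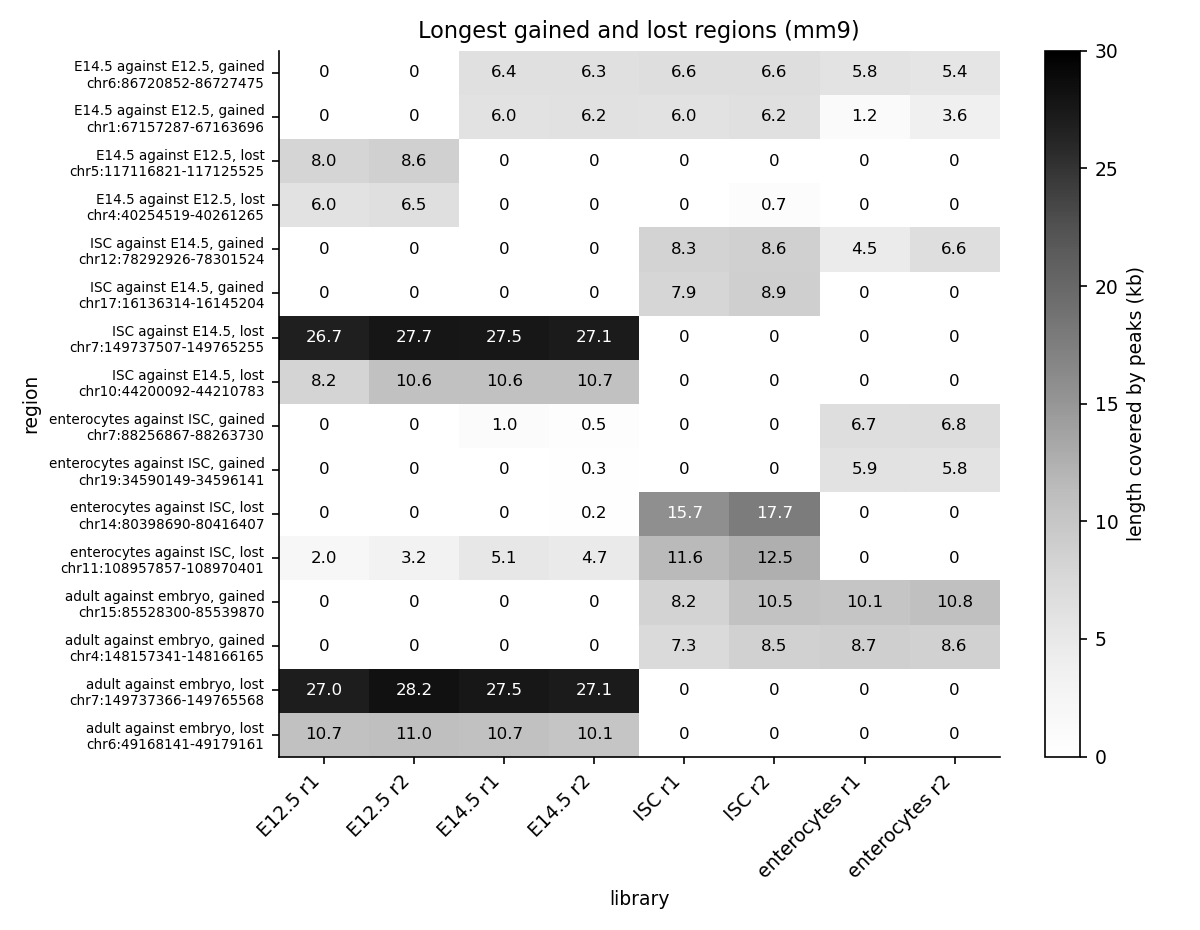
Length covered by peaks, in kb, of the 2 longest gained and the 2 longest lost regions of each comparison in the 8 libraries (r1 and r2 are replicates 1 and 2). The region on chromosome 7 from 149737507 has 26.7 to 27.7 kb in the 4 embryonic libraries and 0 in the 4 adult ones.

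When the peaks of all 8 libraries were merged into 79482 regions, 35967 were present in both or in neither library of every group. Of these, 12282 were common to the 4 groups, 4035 were shared by the embryonic stages alone and 3491 by E12.5, E14.5 and ISC. Regions confined to a single group numbered 3593 in ISC, 3223 at E12.5, 2748 in enterocytes and 2252 at E14.5. Together these were 11816 regions, against at most 7316 in the other 104 ways to pair the libraries. Every other pairing parts replicates, so this difference restates the likeness of replicates. ISC and enterocytes alone shared 1548 regions, and ISC and E14.5 alone shared 1036.

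**Figure D5:**
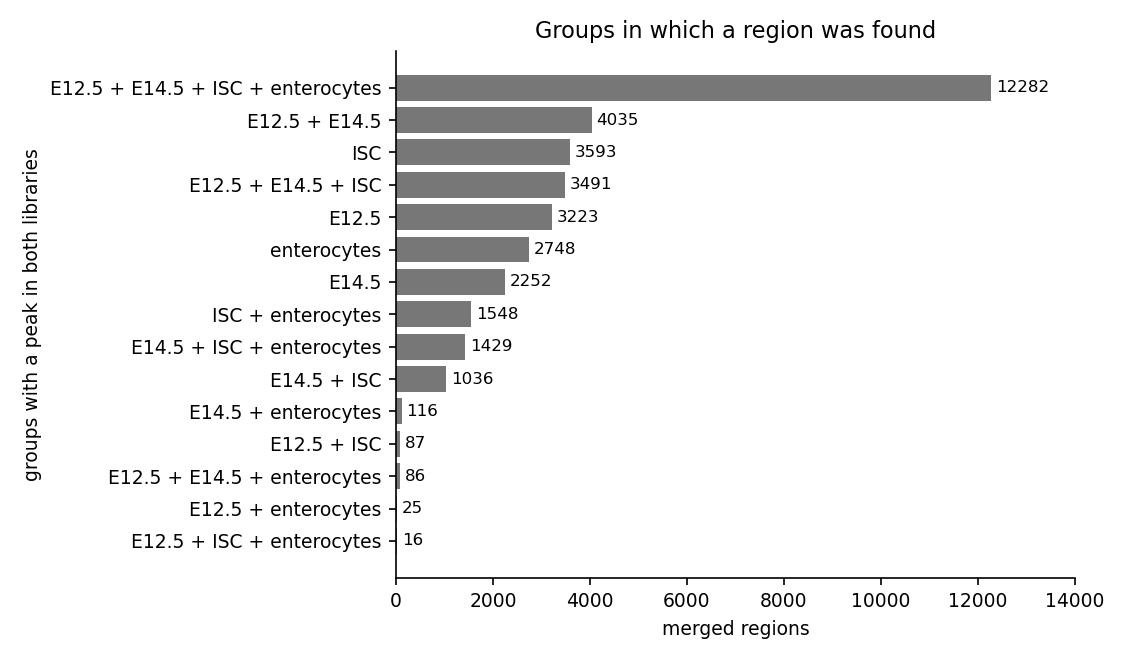
Number of merged regions by the groups in which both libraries had a peak, for the 35967 regions present in both or in neither library of each group. Regions common to the 4 groups lead with 12282, and patterns that skip a group in the order E12.5, E14.5, ISC, enterocytes have at most 116.

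Regions were seldom regained once lost. Of 3533 regions lost between E12.5 and E14.5, 3.11% were present in both ISC libraries and 1.39% in both enterocyte libraries. Of 8039 lost between E14.5 and ISC, 2.86% were present in both enterocyte libraries. Regions gained at E14.5 numbered 6210 in this set, and 44.2% of them were also in both ISC libraries and 27.9% in both enterocyte libraries. Of 6027 regions gained in ISC, 26.7% were in both enterocyte libraries and 63.8% in neither. The 9887 regions lost in enterocytes were of mixed age, with 52.6% present in both E14.5 libraries and 38.9% in neither. Of the 3153 regions gained in enterocytes, 88.8% were in neither E14.5 library.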

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

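The alternatives for the windows, the merging over all 8 libraries and the windows themselves were chosen after seeing the data; the others were fixed before. The alternatives for genes, gene lists and the promoter share that had been planned were not run, because the gene table is on another build. The 16 named regions kept their calls in all 48 values under the stricter threshold, equal peak numbers and the 50% cover; as the longest regions they say little of the others. Leaving out a library cannot end such a call, and the 1 kb merging was not applied to them. The named windows, picked for large changes, gave 272 values under 17 settings, all in the same direction, with adjusted p of at most 0.00781. Replicate overlap was 76.2% for 50% of a peak and 85.8% at equal peak numbers, both within the SD.

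Peaks with −log10 q of at least 10 gave fewer regions, for a reason not tested: 4101 gained and 1135 lost at E14.5, 3602 and 3840 in ISC, 1525 and 6810 in enterocytes, and 915 and 1816 in the adult. Merging within 1 kb gave 4923 gained and 2311 lost at E14.5, 4201 gained in ISC and 1707 gained in enterocytes. The other 26 of 38 region counts lay within 1.5 times. With a library left out, an arm of 1 library meets its criterion more easily. The ranges of gained and lost regions were then 8080 to 15577 and 3957 to 12174 for E14.5, 6699 to 19372 and 8905 to 16807 for ISC, 3301 to 7397 and 11375 to 26922 for enterocytes, and 1553 to 2540 and 4061 to 5605 for the adult. The direction turned for E14.5 without E12.5 replicate 1 (8080 gained, 12174 lost). For ISC it turned without ISC replicate 1 (19372 gained, 8905 lost).

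For windows, 76 of 90 counts lay within 1.5 times. Without scaling 2094 fell at E14.5 and 1552 rose in enterocytes. That setting leaves the differences in total covered length in the values. The means were 51.8 Mb at E12.5, 61.0 Mb at E14.5, 63.7 Mb in ISC and 38.8 Mb in enterocytes. How far other causes add to these counts was not tested. Windows of 50 kb, which are fewer, gave 2834 rises at E14.5, 3313 in ISC, 2733 in enterocytes and 4992 in the adult. The stricter peaks gave 2474 rises and 1556 falls at E14.5, 3163 and 3560 in ISC, 2732 rises in enterocytes and 7866 falls in the adult. The fit with 2 groups gave 3039 rises and 5467 falls in the adult. With a library left out, a lone library was assumed to vary like the other groups. Rises and falls ranged from 1916 to 4440 and 1551 to 3646 at E14.5, 3086 to 5287 and 4063 to 6846 in ISC, 2571 to 4029 and 4862 to 7528 in enterocytes, and 6554 to 7472 and 10111 to 12144 in the adult. Rises at E14.5 fell below falls without either E14.5 library (2038 and 2714 without replicate 1, 1916 and 2183 without replicate 2).

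Replicate numbers did not pair the libraries: deviations of the replicates 1 from their group means correlated between −0.18 and 0.17 over the 6 pairs of groups. With the number as a block, limma called 4032 rises and 3196 falls at E14.5, 4808 and 6277 in ISC, 3850 and 7172 in enterocytes, and 7946 and 12025 in the adult. Depth bounds what can be said of absence: a region without a peak is one that did not pass the authors' threshold at 34.6 to 54.6 M tags.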

Other observations

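The setting with equal numbers of peaks was fixed before the data were examined; the other tests in this part, and the use of that setting to weigh an explanation, were chosen after the results were seen. The regions followed the order E12.5, E14.5, ISC, enterocytes with few interruptions. Of the 35967 regions present in both or in neither library of each group, 330 (0.918%) were present in an earlier and a later group and absent from one between them. The other 11 orders of the 4 groups gave 2692 to 11539 such regions, and the lowest was the order in which E14.5 and E12.5 changed places. Among the few interrupted patterns, 116 regions were in E14.5 and enterocytes alone and 87 in E12.5 and ISC alone.

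Changed regions lay near each other more often than regions drawn at random from the same set. Of regions gained in the adult, 41.3% had another within 50 kb, against 16.5% on average in 10000 random draws, and of those gained in enterocytes 70.5% against 35.8%. For regions lost in enterocytes the shares were 73.7% and 70.4% (permutation p = 0.0001 in each of the 8 sets tested, the smallest these draws can give). The draws take regions as independent, although narrow peaks can split 1 acetylated stretch into several regions. The set drawn from also held regions neither gained, lost nor in all libraries (26988 of 57825 for enterocytes against ISC). These p-values therefore do not tell joint change of separate regions from these features. The 500 kb stretch with the most losses, picked after its values were seen, was on chromosome 8 from 35000001 to 35500000, where 33 of 56 regions were lost between E14.5 and ISC and 7.54 would follow from the genome-wide share. On chromosome 7 from 6500001 to 7000000, 14 of 34 regions were lost between embryo and adult, against 1.73 from that share. Chromosome Y had 17 peaks in ISC replicate 1 and 4 to 6 in the other 7 libraries.

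Enterocytes lost 3.24 regions for each region gained over ISC. Enterocyte libraries had 6.81% fewer tags and 25.3% fewer peaks than ISC. The log-log slope of peaks on tags within the 4 replicate pairs was −0.0255 (SE 0.287). Raised by 2 SE it gives a deficit of 3.80%, but it used ChIP tags before scaling to the input and bounds depth loosely. Single libraries were also compared. Enterocytes replicate 1 had more ChIP tags than either ISC library. Against it, ISC replicates 1 and 2 had 1.87 and 3.96 regions of their own per enterocyte region. Against enterocytes replicate 2, which had fewer tags, the values were 2.05 and 4.71. These ratios argue against lower depth as the whole cause. The excess of losses was not confined to weak peaks near the threshold. Some regions had −log10 q of at least 10 in both libraries of one group and no peak in the other group. Among these the ratio was 5.13 (4200 lost, 818 gained). That cutoff kept 26380 and 29981 peaks in the ISC lists and 21068 and 20125 in the enterocyte lists, which may favour losses. By −log10 q, the median lost region stood at the 34th percentile of the ISC lists. The median gained region stood at the 26th of the enterocyte lists, and regions in all libraries at the 64th. Weak peaks therefore stay open as a part of the excess. With equal numbers of peaks per library the ratio was 1.70, but equal numbers remove part of any real deficit, so fewer called peaks and a smaller active genome cannot be told apart here. A loss of active regions on differentiation remains a hypothesis, and the yield of the immunoprecipitation stays open beside it.

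Regions gained at E14.5 were less often in both ISC libraries (44.2%) than regions of both embryonic stages (74.0%), and peak strength or length may account for this. Matched in 10 classes of −log10 q rank within the E14.5 lists, the difference turned to +12.1 percentage points (SE 1.03 over chromosomes), and matched on length it was −0.37 (SE 1.14). Matched on both, the gained regions were ahead by 13.0 points for ISC (SE 1.07) and 16.1 for enterocytes (SE 0.714), so length does not account for the pooled lead at equal strength. The lead was not uniform: for ISC it was 9.11 and 14.6 points below the 25th and from the 25th to the 50th percentile, 2.48 up to the 75th and −9.17 above it, where 34 gained regions stood, and for enterocytes 11.8, 17.5, 12.3 and −10.1. For regions gained in ISC, the share kept in enterocytes minus that of regions shared with E14.5 was −40.8 points unmatched, −4.48 matched on strength (SE 0.787) and −3.92 on both (SE 0.734), with −2.66, −3.18, −16.1 and −36.1 in these classes of the ISC lists (88 gained regions in the last), and no biological explanation of either difference was tested.

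Adult and embryo differed in 5583 regions and, in a fit with 2 groups, in 8506 windows. Only 3 splits of the libraries keep replicates together, too few for a share under 0.05: the real one is 1 of the 3 for regions (highest other 1061) and 1 of the 3 for windows (highest other 214). The number of peaks called is argued against as the whole cause of the total, since 4640 regions were gained or lost with equal numbers of peaks per library. The ratio of lost to gained regions fell from 2.61 to 1.71 in that setting (2926 lost, 1714 gained). Peak numbers therefore stay open as a part of the excess of losses. Age, cell type and the way the cells were isolated differ between these groups and stay open, as does sex, which is given only for the adults.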
